A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

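The series holds MNase-seq of wild-type W303 Saccharomyces cerevisiae in 4 libraries. Per the labels' protocols, log cells were harvested at an OD600 of 0.4 to 0.6 and Q cells were purified on Percoll gradients from cultures of 7 days, spheroplasts were made with zymolyase, chromatin was digested with micrococcal nuclease and exonuclease III, and mononucleosome-size DNA was made into TruSeq libraries and sequenced from both ends. Each condition had a digest with 50% and one with 80% mononucleosomes, and the series text calls the digests matched and the isolates independent, without tying a library to an isolate. The submitters' processing notes name CASAVA, TopHat2 and SAMtools with no versions given in the sources used here, and state no roles for them.

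Each deposited file holds a per-base signal over 17 chromosomes and 12157088 bases. In all files 100% of the low values (up to 20 steps) were whole multiples of one step within 0.1 step, and the values rise and fall as counts of points rather than as coverage of whole fragments. Dividing by that step recovered 60.8 (log 50%), 17.6 (log 80%), 65.7 (Q 50%) and 43.4 (Q 80%) M positions, of which 55.1, 13.8, 58.1 and 38.5 M were nuclear outside the ribosomal DNA. The plan had assumed coverage, so that the planned 100-bp windows held fewer data than foreseen, with a median near 0, and this limits all values in them. The build is not named in the sources used here. Each of the 17 chromosomes was 1 bp shorter than in the R64 assembly, and gene positions were taken from a gene table of that assembly. Coordinates printed are those of the files. How positions that align to several places were treated is not given in the sources used here.

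Each library was scaled to a mean of 1 over nuclear chromosomes without the ribosomal DNA (chromosome XII from 451575 to 489469). Of 6002 nuclear protein-coding genes 19 lay within 500 bp of a chromosome end or in the ribosomal DNA and were left out, as were 13 with a mean under 0.2 within 500 bp of the start codon, which left 5970. The NDR was the 100-bp window with the lowest mean over the 4 libraries within 400 bp upstream of the start codon, with a median centre 161 bp upstream. Choosing the window on the same libraries favours low values in all of them. Genes whose window lay at the upstream limit of the search were kept. The +1 position was the maximum of the signal smoothed with a Gaussian (SD 20 bp) within 250 bp downstream of the NDR centre. Genes with a maximum at the edge of that range in any library were left out of the comparison of positions. The +1 signal, in the fixed window and at each library's own maximum, kept these genes. The +1 signal was the mean over 100 bp at the position found on the mean of the 4 libraries. Gene bodies ran from 500 bp inside the coding region, for coding spans of at least 1000 bp, and terminators were the lowest 100-bp window within 300 bp of the stop codon. Nucleosome calls were maxima at least 100 bp apart and above the genome mean of 1, and were shared if within 20 bp. The chance share was measured with the calls of one library shifted along the chromosomes.

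The comparison of Q with log was fitted in limma on log2(scaled signal + 0.1) with condition and digestion level as terms, variances moderated with a trend and robustly, 1 residual degree of freedom, and a Benjamini-Hochberg adjusted p of 0.05. Positions were fitted in bp. The 32 gene lists, the window definitions, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, adjusted over the lists), and for the planned NDR window also with fry and an estimated correlation. The estimated form rests on the 1 residual degree of freedom and has little power here. For stress genes in the 100-bp window the estimate (-0.014) was below the preset, yet camera p went from 9.85e-05 to 0.128. For ribosomal proteins the estimate was 0.127. List tests on the +1 signal, the +1 position, gene bodies and the 200-bp window were chosen after the data were examined. Named genes were the 10 largest differences in each direction past the threshold with one sign in both digest pairs, with up to 4 such members of each list, or, where none passed, the 5 largest in each direction as values with no call. Divergent genes that share a window were named together, and genes of near-identical families were treated as uncertain. Repeat length was the slope through the peaks +1 to +5 of the average profile and amplitude the mean of peak minus following trough, each compared by an exact permutation test.

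On simulated data with 200 changed genes at a dispersion of 0.02, limma recovered 0% of 2-fold and 0% of 4-fold changes in the 100-bp window, 0% and 89.5% in the 200-bp window and 90% and 99.5% for the +1 signal (3 and 11 false calls). By edgeR the shares were 7% and 56.5%, 61.5% and 98%, and 89% and 99.5%. Shifted +1 positions, simulated with a noise of SD 3 bp, were recovered in 100% of cases with 9 false calls, and a simulated repeat of 165 bp gave 165 bp. A count of 0 by limma in the 100-bp window therefore has no power behind it at these changes. The simulations held no digestion effect. In the data a position difference of 165 bp (limma adjusted p = 0.128) and a +1 signal difference of 3.62 ± 1.196, both at CCW12, did not pass. By edgeR no gene passed in the 200-bp window. There DPS1 went from 0.067 in log to 0.80 in Q at 50%, and from 0.0087 to 0.77 at 80%. The simulated recovery for positions, for the +1 signal and by edgeR in the NDR windows is therefore no measure of power in these data.

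The settings varied by plan were other pseudocounts, deposited values without scaling, quantile normalization, no filter, no digestion term, plain variance moderation, each library left out, other windows, other smoothing and other limits for calls. In the fits without a library the lone library of its condition was assumed to vary like the others. Chosen after the data were examined were edgeR on recovered positions, thinning to the shallowest library and scaling relative to the 1000 bp around the start codon. Software was R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. GC content was not analysed here.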

Results

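Nucleosome positions were mapped in wild-type W303 budding yeast by MNase-seq, in which micrococcal nuclease trims chromatin to nucleosome cores and the protected DNA is sequenced. Cells growing exponentially (log) were compared with quiescent (Q) cells, the dense, non-dividing fraction that sediments in a Percoll gradient, here from stationary cultures of 7 days. Each condition had 2 libraries (n = 2), one from a digest with 50% mononucleosomes and one from a digest with 80%. The log libraries held 60.8 M (50%) and 17.6 M (80%) sequenced positions, and the Q libraries held 65.7 M (50%) and 43.4 M (80%). In the log 80% library 62.7% of bases had no position, against 25.0% in log 50%, 26.3% in Q 50% and 34.3% in Q 80%. The libraries of one condition differ in digestion, and the labels used here do not tie a library to an isolate, so that n counts libraries and not known independent cultures. Differences below are Q minus log on the log2(scaled signal + 0.1) scale, which understates the change of low values, with the standard error (SE) of a limma fit to all 4 libraries with digestion level as a term. Fits that leave out a library have condition as the single term, so that they compare unequal digests and change with digestion as well as with the library. The question was where along genes nucleosomes of Q cells differ from those of log cells.

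The +1 nucleosome, the first one downstream of the promoter's nucleosome-depleted region (NDR), carried more signal in Q cells at genes for cytosolic ribosomal proteins and for glycolysis, and less at general stress genes, relative to other genes. The 137 ribosomal protein genes had a median difference of 1.33, against 0.43 over all 5970 genes. A +1 maximum inside the search range in each library was found at 55 of these 137, and at 3871 of all genes. It was found at 16 of 23 glycolysis genes and 29 of 61 stress genes. At the remaining genes, kept here, the +1 nucleosome is uncertain. Their median was 0.93 in the 50% pair and 2.07 in the 80% pair, and 111 of them were higher and 4 lower in both pairs. The 23 genes of glycolysis and fermentation had a median of 1.04 (0.71 at 50%, 1.80 at 80%). The 61 general stress genes, a set driven by the transcription factors Msn2 and Msn4, had a median of -0.37 (-0.70 at 50%, -0.084 at 80%), with 30 lower and 12 higher in both pairs. These lists were fixed before the data were examined, but testing them on the +1 signal was decided afterwards. With a preset inter-gene correlation, limma's camera ranked ribosomal proteins above other genes (adjusted p = 2.05e-10), as it did glycolysis (adjusted p = 0.00969), and stress genes below them (adjusted p = 2.53e-13). These p-values, here and below, rank genes against other genes within the 4 libraries. They do not measure how a difference repeats between cultures. With an estimated correlation none of the 32 lists passed (adjusted p = 0.979 for each). That form rests on 1 residual degree of freedom. Its losses, here and below, therefore cannot tell correlated genes from a lack of power. The ribosomal protein and stress calls held with each of the 4 libraries left out, while glycolysis passed in 2 of those 4 fits. At each library's own +1 maximum, rather than in a fixed window, the gap between ribosomal protein and stress genes was 1.202 against 1.62 in the 50% pair and 1.85 against 2.15 in the 80% pair. Quantile normalization moved the all-gene median to 0.033 and scaling to the 1000 bp around each start codon moved it to 0.25, and these 3 lists kept their directions under both. That median was -0.019 without the log 80% library and 0.95 without the log 50% library, in fits of unequal digests.

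Among single genes, MRK1, which encodes a kinase of the GSK-3 family, was the one that passed the test on the +1 signal. Its signal fell by 3.58 ± 0.79 (SE, n = 2 per condition, limma adjusted p = 0.0386), from 3.19 and 9.75 in the log 50% and log 80% libraries to 0.582 and 0.231 in the matching Q libraries, where 1 is the nuclear mean. Other settings called more genes: 215 higher and 268 lower with quantile normalization, and 84 and 43 without trend or robust moderation. MRK1 was among the lower genes in both. In the main fit the largest differences in the other direction, none past the test, were at CCW12, a cell wall mannoprotein (3.62 ± 1.196), TPI1, triose phosphate isomerase (3.36 ± 1.23), the ribosomal protein genes RPL2A (3.23 ± 1.24) and RPS24B (3.08 ± 1.21), and the +1 nucleosome shared by MIN4 and ERG6, the latter a sterol methyltransferase (3.33 ± 0.91). The NDR centres of MRK1, ERG6 and RPS24B lay at -351 bp from the start codon, the upstream limit of the search. Those of TPI1 (-350 bp) and CCW12 (-346 bp) lay next to it. Whether the true NDR of these genes lies farther upstream was not tested, so their +1 nucleosome is uncertain. No ribosomal protein or glycolysis gene passed over all genes or adjusted over the list alone. No stress gene passed over all genes, and 10 of 61 were lower adjusted over the list alone. Of these, chosen after their values were seen, HSP12, a small heat shock protein, differed by -2.46 ± 0.59 (adjusted p = 0.0587), the chaperone gene HSP26 by -2.03 ± 0.55, the reticulon gene RTN2 by -2.32 ± 0.69 and DDR2 by -2.04 ± 0.59. The +1 maximum of HSP26 also lay farther upstream in Q cells (below), so its fixed window can miss a nucleosome that moved. Without either Q library, without the digestion term, with a pseudocount of 0.02 or with values as deposited no gene passed. Without the log 50% library 4249 did and without the log 80% library 174 did, and edgeR called 13 (3 higher, 10 lower).

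**Figure D1:**
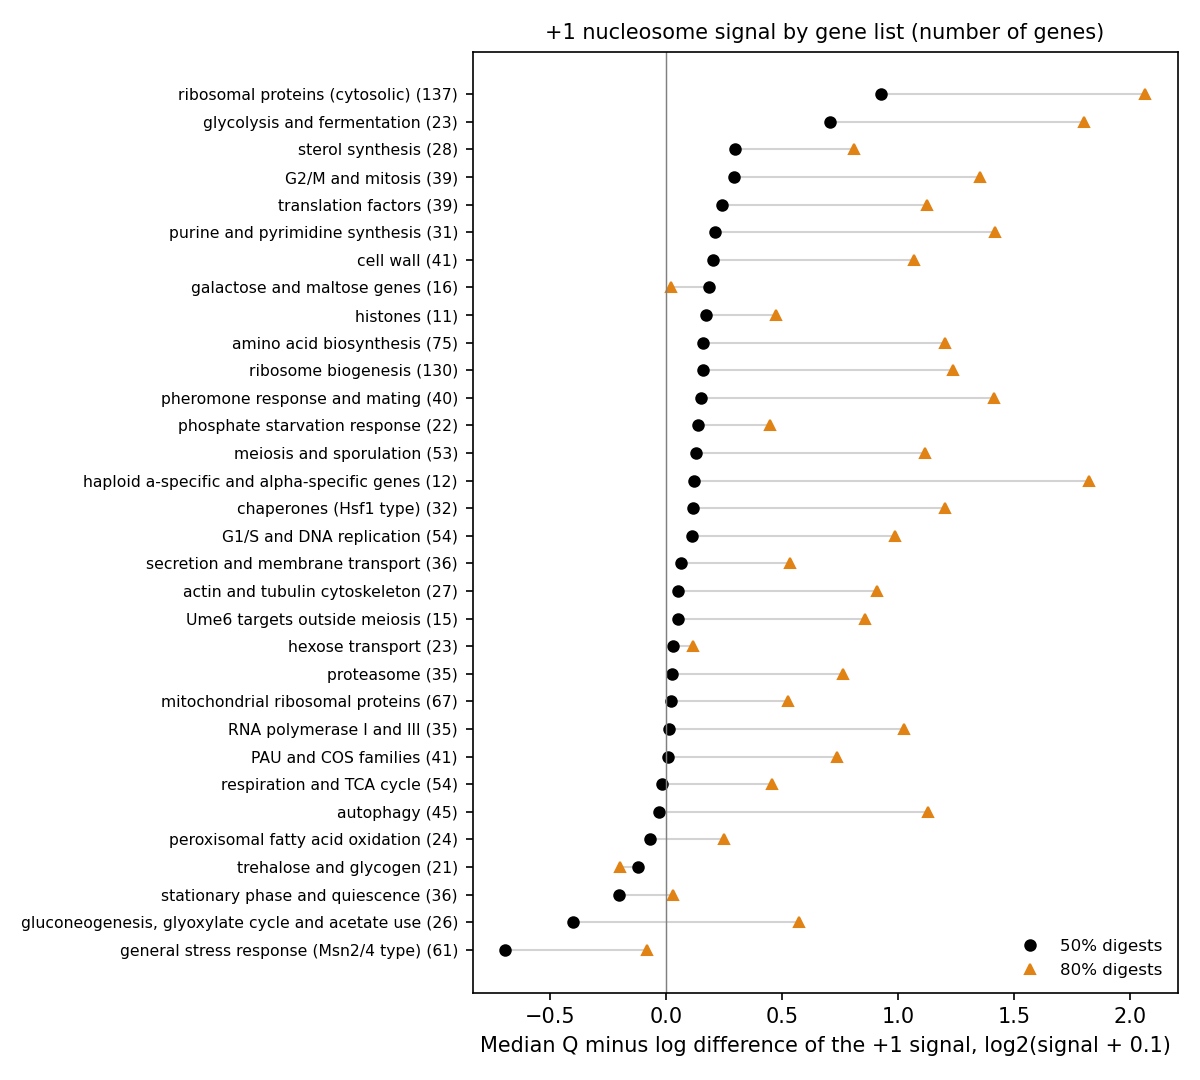
Median Q minus log difference of the +1 nucleosome signal, log2(scaled signal + 0.1), for each gene list with its number of genes, in the 50% digests (black circles, 1 library per condition) and the 80% digests (orange triangles). Ribosomal proteins lie highest in both pairs (0.93 and 2.07), and the general stress list lies lowest in the 50% pair (-0.70).

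The same test placed 5 further lists apart from other genes on the +1 signal. Ribosome biogenesis factors ranked higher (130 genes, median 0.68, adjusted p = 0.0405, and adjusted p = 0.979 with an estimated correlation). Genes of gluconeogenesis and the glyoxylate cycle (26 genes, median 0.098, adjusted p = 0.00288), trehalose and glycogen metabolism (21 genes, median -0.14, adjusted p = 0.00724), stationary phase and quiescence (36 genes, median -0.014, adjusted p = 5.11e-04) and peroxisomal fatty acid oxidation (24 genes, median 0.072, adjusted p = 0.0405) ranked lower than other genes. Each of these calls was lost with an estimated correlation (adjusted p = 0.979). The gluconeogenesis and peroxisomal medians were above 0 but below the all-gene median of 0.43 (0.056 at 50%, 0.84 at 80%). No member passed over all genes, and adjusted over the list alone 2 gluconeogenesis genes and 3 stationary phase genes were lower, with 0 in the other 3 lists. With scaling to the 1000 bp around the start codon none of these 5 lists passed. Ribosome biogenesis and peroxisomal genes passed in 1 of the 4 fits that leave out a library, and the other 3 lists in 3 of 4.

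The position of the +1 nucleosome shifted by little at most genes. Over 3871 genes with a +1 maximum in all libraries the median difference was -4 bp, upstream in Q cells, and 79.8% of genes differed by under 20 bp. Both pairs put the Q nucleosome upstream at 2125 genes and downstream at 729. No gene passed the limma test, 239 were downstream and 757 upstream at an unadjusted p under 0.05, and no other tool was run on positions. Without the digestion term 86 genes passed downstream and 142 upstream. Leaving out the log 50% library gave 40 and 85.

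Genes for storage carbohydrates and chaperones that could be measured went against that direction, with +1 nucleosomes farther downstream in Q cells. Those with a maximum at the edge of the search range were left out, a filter that depends on the position itself. It left 9 of 21 trehalose and glycogen genes, 19 of 32 chaperone genes and 29 of 61 stress genes. The 9 measured genes of trehalose and glycogen metabolism had a median difference of 44 bp, with 8 downstream in both pairs and 5 past the test adjusted over the list alone. They include ATH1, acid trehalase (99.5 ± 2.10 bp), GLG1, a glycogenin that primes glycogen synthesis (60.5 ± 0.64 bp), GPH1, glycogen phosphorylase (44 ± 3.30 bp), and GLC3, the branching enzyme (30 ± 0.53 bp). The 19 chaperone genes had a median of 5.5 bp, with 11 downstream and 2 upstream in both pairs and 4 past the test adjusted over the list alone: HSP33 (75 ± 0.95 bp), the mitochondrial disaggregase gene HSP78 (72.5 ± 3.70 bp) and the Hsp70 genes SSA3 (62 ± 0.95 bp) and SSA1 (53 ± 2.49 bp). HSP33 belongs to a family of near-identical copies and is uncertain. The 29 general stress genes had a median of 14.5 bp, and members went both ways: adjusted over the list alone 3 lay downstream, among them STF2 (134.5 ± 0.64 bp), and 2 upstream, HSP26 (-70.5 ± 0.64 bp) and the hexose transporter gene HXT5 (-87 ± 3.30 bp). These members were chosen after their values were seen. The SEs of positions, here and below, rest on 1 residual degree of freedom and follow how closely the digest pairs happened to agree. A small SE is therefore no measure of precision, and the calls adjusted over the list alone rest on these SEs. PST1, for instance, differed by 158 ± 0.95 bp (159 bp at 50% and 157 bp at 80%) and did not pass over all genes (limma adjusted p = 0.123). Camera, applied to positions after the data were examined, placed trehalose and glycogen (adjusted p = 3.18e-06), chaperones (adjusted p = 1.20e-04) and stress genes (adjusted p = 7.55e-04) downstream of other genes with each library left out. None of them passed with an estimated correlation (adjusted p = 0.810). Autophagy genes (26 genes, median 2.75 bp, adjusted p = 0.0163) and gluconeogenesis genes (16 genes, median 2.75 bp, adjusted p = 0.0394) passed in 2 of those 4 fits, with 0 members past the test over all genes or adjusted over the list alone. These calls too were lost with an estimated correlation (adjusted p = 0.810).

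The largest single displacements approached the distance between neighbouring nucleosomes, so that the maximum in one condition can belong to another nucleosome of the same array. Downstream in Q cells these were CCW12 (169 bp at 50% and 161 bp at 80%, SE 3.30 bp), COI1 (161 ± 2.49 bp), the cell wall gene PST1 (158 ± 0.95 bp), GLN1, glutamine synthetase (147 ± 2.49 bp), and ERG29, a sterol gene (137 ± 4.11 bp). Upstream they were PRM10 (-160.5 ± 4.51 bp), SBH2 (-150.5 ± 2.90 bp), DGA1, a diacylglycerol acyltransferase that makes storage lipid (-141 ± 0.95 bp), MAK11 (-140 ± 7.36 bp) and DLD3, a lactate dehydrogenase (-134 ± 5.73 bp). None passed over all genes (lowest adjusted p among them 0.123). In log cells the CCW12 maximum lay 26 and 33 bp from the NDR centre at 50% and 80%. That is inside the 100-bp NDR window, so it need not mark a +1 nucleosome. The NDR centres of COI1 and PRM10 (-351 bp from the start codon) and of PST1 and GLN1 (-350 bp) lay at the upstream limit of the search. That of CCW12 (-346 bp) lay near it, so the +1 nucleosome of these genes is uncertain. CCW12, which led the +1 signal differences named above, is thus also among the largest in position. In total 48 genes differed by over 100 bp in one direction in both pairs.

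**Figure D2:**
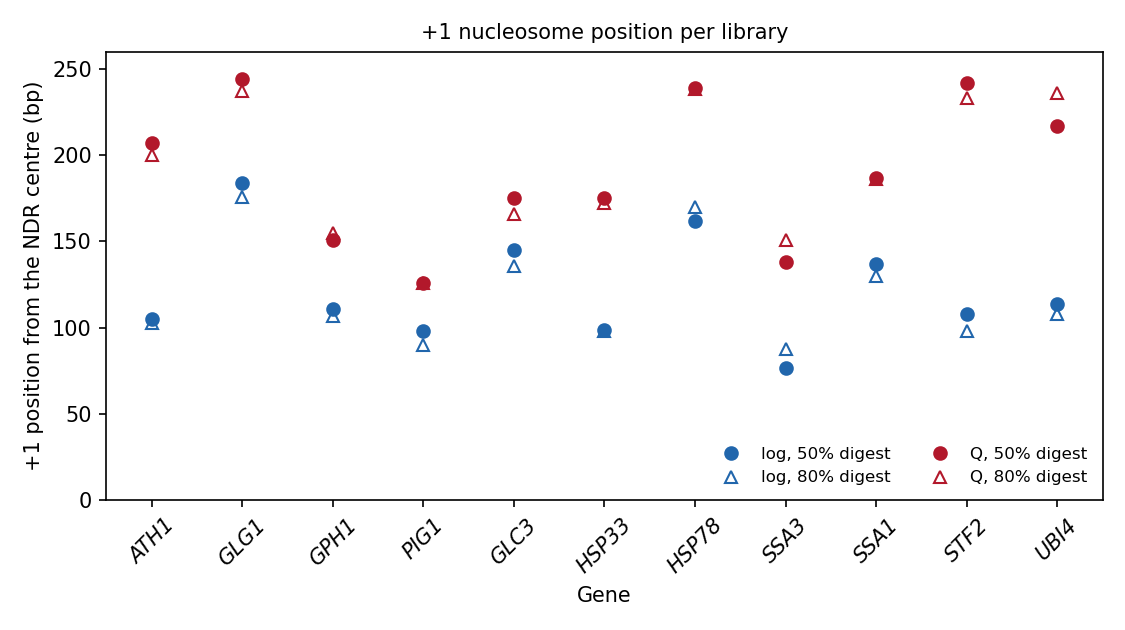
Distance of the +1 nucleosome from the NDR centre in bp, downstream positive, for genes of storage carbohydrate metabolism (ATH1, GLG1, GPH1, PIG1, GLC3), chaperones (HSP33, HSP78, SSA3, SSA1) and the stress list (STF2, UBI4), one point per library. For each gene plotted, chosen after its values were seen, both Q libraries (red) lie downstream of both log libraries (blue), as for ATH1 at 105 and 103 bp in log against 207 and 200 bp in Q.

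In the NDR itself, the size of the difference in nucleosome signal between Q and log cells depended on the pseudocount and the tool. Its all-gene median was above 0 in both digest pairs and, barely, relative to the 1000 bp around the start codon (0.018, 51.5% of genes higher). It turned in some fits of unequal digests (below). Quantile normalization, here and below, gives all 4 libraries one distribution. That holds all-gene medians near 0, so it cannot test their direction. In the least covered 100-bp window upstream of each start codon the median difference over 5970 genes was 0.099, with 0.080 in the 50% pair and 0.087 in the 80% pair. That median was 0.32 with a pseudocount of 0.02, 0.022 with one of 0.5 and 0.64 by edgeR on recovered positions. The median window held 0.0371 (log 50%), 0 (log 80%), 0.0518 (Q 50%) and 0.0156 (Q 80%) of the nuclear mean, so that the windows hold very few positions. No gene passed the limma test, and 316 were higher and 30 lower at an unadjusted p under 0.05. With scaling to the 1000 bp around the start codon 33 passed as higher and 1 as lower. By edgeR no gene passed either, with 35 higher and 22 lower unadjusted. The largest values with no call were higher at UTR5 (2.85 ± 0.62, window on chromosome V from 85546 to 85645), HSP33 (2.14 ± 0.50), PMA2, a minor plasma membrane proton pump (2.09 ± 0.51), AQY1, a water channel (2.09 ± 0.50), and MEP2, an ammonium permease (1.93 ± 0.51). They were lower at PAU10 (-2.20 ± 0.50), SPG4 (-1.83 ± 0.50, chromosome XIII from 482880 to 482979), IGD1, an inhibitor of glycogen debranching (-1.69 ± 0.31), ZPS1 (-1.69 ± 0.55) and AAD3 (-1.52 ± 0.49). PAU10, HSP33 and AAD3 belong to families of near-identical copies and are uncertain. Without the log 50% library 249 genes passed as higher and 27 as lower, and without the log 80% library 9 and 54, while none passed without either Q library. In these fits, which compare unequal digests, the all-gene median was -0.032 without the log 80% library, -0.043 without the Q 50% library, 0.28 without the log 50% library and 0.26 without the Q 80% library. Quantile normalization gave a median of -0.022, with 113 genes higher and 204 lower at an unadjusted p under 0.05. The differences of the 50% and 80% pairs correlated weakly across genes (Pearson r = 0.167, Spearman rho = 0.112, 54.5% of genes with the same sign), and genes are not independent replicates.

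A 200-bp window, planned as an alternative and taken as a result of its own after the data were examined, held more signal. The median was 0.41 (0.28 at 50%, 0.53 at 80%), and 71.4% of genes had the same sign in both pairs. By edgeR on recovered positions, with all 4 libraries, the median was 1.12. In limma fits of unequal digests the median was 0.042 without the log 80% library, 0.15 without the Q 50% library, 0.77 without the log 50% library and 0.68 without the Q 80% library. Signal rose at 24 genes and fell at 4, a balance that turned with quantile normalization (42 higher, 95 lower) and, in a fit of unequal digests, without the log 80% library (6 higher, 15 lower). Of the 24 higher genes 2 kept their call with quantile normalization, 2 without the log 80% library and 7 without the log 50% library, and of the 4 lower genes 4, 2 and 2 did. Among those that rose were DPS1, aspartyl-tRNA synthetase (2.72 ± 0.64), TPI1 (2.44 ± 0.66), RAX1, a bud-site selection protein (1.91 ± 0.51), ADH6, an alcohol dehydrogenase (1.77 ± 0.46), INA1 (1.76 ± 0.46), ACT1, actin (1.64 ± 0.43), ARO1, an enzyme of aromatic amino acid synthesis (1.55 ± 0.40), APL4, a clathrin adaptor subunit (1.32 ± 0.34), PXR1, a ribosome biogenesis factor (1.30 ± 0.29), and RET1, a large subunit of RNA polymerase III (1.27 ± 0.29), with adjusted p from 0.0306 to 0.0474. Of the listed groups, the ribosomal protein genes RPS14B (0.71 ± 0.18), in a window shared with SOP4, and RPS16A (0.52 ± 0.14), URA1 of pyrimidine synthesis (1.003 ± 0.26) and the proteasome gene RPN3 (0.62 ± 0.17) also rose. Signal fell at NDE2, a mitochondrial NADH dehydrogenase (-3.09 ± 0.75), SPG1, a stationary phase gene (-2.73 ± 0.72), and the window shared by CSM4 and YIG1 (-1.60 ± 0.42). Without either Q library, without the digestion term or by edgeR no gene passed (edgeR gave 203 higher and 26 lower at an unadjusted p under 0.05). Without the log 50% library 1252 passed as higher and 89 as lower.

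General stress genes had less NDR signal in Q cells relative to other genes. In the 100-bp window their median was -0.0011 against 0.099 for all genes (camera adjusted p = 0.00315), and in the 200-bp window it was -0.16 against 0.41 (adjusted p = 3.44e-15), where no member passed over all genes and 1 was lower adjusted over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.957 and 0.770). Ribosomal protein genes ranked higher in the 100-bp window (median 0.26, adjusted p = 0.00656), as did ribosome biogenesis (median 0.11, adjusted p = 0.0385), while hexose transporters (median -0.059, adjusted p = 0.0268) and the near-identical PAU and COS families (median 0, adjusted p = 0.00656) ranked lower. With an estimated correlation none of these passed either (adjusted p = 0.957), nor did any list by fry in the 100-bp window, where no member passed over all genes or adjusted over the list alone. Relative to the 1000 bp around each start codon the 100-bp order turned, with ribosomal proteins lower (median -0.38, adjusted p = 4.54e-06) and stress genes higher (median 0.39, adjusted p = 4.85e-04). Those 1000 bp hold the +1 nucleosome, whose signal was higher at ribosomal proteins (median 1.33) and lower at stress genes (-0.37). The direction of these NDR differences thus depends on the scaling, but the turn can follow from the +1 signal alone, which was not tested. In the 200-bp window that scaling put ribosomal proteins lower too (median -0.18, adjusted p = 2.03e-10), and stress genes no longer passed (adjusted p = 0.157). Quantile normalization moved the all-gene median from 0.099 to -0.022 in the 100-bp window and from 0.41 to 0.0090 in the 200-bp window. With it stress genes (adjusted p = 0.0890), ribosome biogenesis (adjusted p = 0.942) and hexose transporters (adjusted p = 0.418) no longer passed in the 100-bp window, while stress genes stayed lower in the 200-bp window (adjusted p = 1.45e-17). In 3 of the 4 fits that leave out a library no list passed in the 100-bp window.

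In the 200-bp window 8 lists besides the stress genes passed, each lost with an estimated correlation (adjusted p = 0.839 for ribosomal proteins and 0.770 for the other 7). Ribosome biogenesis (median 0.29, adjusted p = 5.59e-07), ribosomal proteins (0.43, adjusted p = 0.00273) and RNA polymerase I and III (0.39, adjusted p = 0.00463) ranked higher, although the first and last medians lay below the all-gene 0.41, as the test uses moderated statistics rather than medians. None of these 3 ranked higher with quantile normalization or relative to the 1000 bp around the start codon. Stationary phase and quiescence genes (0.13, adjusted p = 5.59e-07), trehalose and glycogen (0.23, adjusted p = 0.00273), gluconeogenesis (0.17, adjusted p = 0.0103), PAU and COS families (0.41, adjusted p = 0.0151) and hexose transport (0.25, adjusted p = 0.0247) ranked lower. Quantile normalization ended the PAU and COS and hexose calls, and scaling to the 1000 bp around the start codon ended all 5. Only the stress list passed with each library left out, and the ribosomal protein list pointed the other way in 2 of those 4 fits, without the log 50% library (adjusted p = 0.427) and, past the threshold, without the Q 50% library. Ribosome biogenesis, RNA polymerase I and III and hexose transport each pointed the other way in 1 fit, without the log 50% library, where none of them passed. Over all genes 2 ribosomal protein genes, 1 gene of RNA polymerase III and 1 stationary phase gene passed, and adjusted over the list alone 24 ribosome biogenesis genes, 2 ribosomal protein genes and 6 RNA polymerase genes were higher and 3 stationary phase genes lower. Trehalose and glycogen (1 higher, 2 lower), stationary phase (1 higher) and PAU and COS genes (1 higher, 1 lower) had members past the test in this way as well, and the other lists had 0.

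Over gene bodies, from 500 bp inside the coding region to the stop codon, signal was higher in Q cells at ribosome biogenesis genes and lower at stress genes relative to others. The 91 ribosome biogenesis genes had a median of 0.27 against 0.044 for all 3579 genes, with 65 higher and 4 lower in both pairs, and 0 past the test over all genes or adjusted over the list alone. The 32 stress genes had a median of -0.29, with 21 lower and 0 higher in both pairs. Among them PRB1, vacuolar proteinase B, was the single gene of all 3579 to pass, and fell by 0.97 ± 0.22 (adjusted p = 0.0421), from 0.835 and 3.15 in log to 0.622 and 0.988 in Q at 50% and 80%. Adjusted over the list alone 2 stress genes were lower. Camera, applied here after the data were examined, gave an adjusted p of 3.26e-05 for ribosome biogenesis and of 1.30e-05 for stress genes, both lost with an estimated correlation (adjusted p = 0.822). Both held with each library left out. Relative to the 1000 bp around the start codon ribosome biogenesis no longer passed (median -0.051 against -0.059 for all genes) and stress genes turned higher (median 0.056, adjusted p = 0.0306). That region holds the +1 nucleosome, whose signal was lower at stress genes, so their turn can follow from it, which was not tested.

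The largest gene body values with no call were higher at NOP53, a ribosome biogenesis factor (1.33 ± 0.66), LIN1 (1.24 ± 1.04), TRM82, part of a tRNA methyltransferase (1.08 ± 1.04), VPS38 (0.92 ± 0.75) and KRE28, a kinetochore protein (0.91 ± 1.21). Glycolysis (18 genes, median -0.31, adjusted p = 5.67e-05), respiration (20 genes, -0.28, adjusted p = 9.69e-04), gluconeogenesis (22 genes, -0.23, adjusted p = 0.00539) and chaperones (22 genes, -0.15, adjusted p = 0.0339) ranked lower on gene bodies. These 4 calls were lost with an estimated correlation (adjusted p = 0.822) and passed in 2, 2, 3 and 2 of the 4 fits that leave out a library. Over all genes 0 of their members passed, and adjusted over the list alone 1 chaperone gene was lower. With quantile normalization none of the 4 passed, and relative to the 1000 bp around the start codon glycolysis alone did. Without the log 80% library the glycolysis list was higher past the threshold (adjusted p = 0.00377), and respiration and chaperones pointed higher without passing. PRB1 did not pass with quantile normalization, with scaling to the 1000 bp around the start codon, with plain variance moderation or by edgeR, which called no gene on bodies (99 higher and 77 lower at an unadjusted p under 0.05), and no gene passed without either Q library. Without the log 50% library 2136 genes did, PRB1 among them, and without the log 80% library 1 other gene did. Without the digestion term no gene passed.

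Downstream of stop codons and over tRNA genes, the median difference between Q and log had opposite signs in the 50% and 80% digests. The least covered 100-bp window within 300 bp of the stop codon had a median difference of 0.081 over 5965 genes, -0.090 at 50% and 0.28 at 80%, and of -0.024 with quantile normalization. That median was 0.33 with a pseudocount of 0.02, 0.010 with one of 0.5 and 0.65 by edgeR. No gene passed by limma (86 higher and 101 lower unadjusted) or edgeR (2 and 9), and no gene list passed. The largest values were higher at VVS1 (2.23 ± 0.85), PET130 (2.19 ± 0.90), RTS2 (2.16 ± 0.95), ICL1, isocitrate lyase (2.08 ± 0.93), and PFU1 (1.96 ± 0.95), and lower at TRS23, a subunit of a vesicle tethering complex (-2.39 ± 0.87), CAX4 (-2.24 ± 0.73), MIN9 (-1.98 ± 0.91), RDS1 (-1.53 ± 0.95) and AAR2, a splicing factor (-1.51 ± 0.90). Over 273 tRNA genes the median was -0.16, with 0.54 at 50% and -0.79 at 80%, and of -0.057 with quantile normalization. No tRNA gene passed by limma or edgeR, and 0 did at an unadjusted p under 0.05 by either. With quantile normalization limma called 21 higher and 15 lower. Among tRNA genes with a standard symbol, the largest values that kept their sign in both pairs were higher at TRN1 (0.60 ± 0.60), SUF6 (0.58 ± 1.09) and SUF9 (0.34 ± 0.53) and lower at SUF1 (-1.43 ± 1.24), SUF10 (-1.34 ± 1.26), TGA1 (-1.23 ± 1.22), TRT2 (-1.03 ± 1.25) and SUP56 (-0.95 ± 1.19).

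Regular nucleosome arrays ran downstream of the +1 nucleosome in both conditions with nearly the same spacing. Over 3579 genes with a coding span of at least 1000 bp, the repeat length was 164.8 and 164.2 bp in the log 50% and 80% libraries and 165.3 bp in both Q libraries, a difference of 0.8 bp (exact permutation p = 0.333, the smallest that 2 against 2 can give). The mean amplitude from peak to following trough in Q was 1.77 and 1.67 at 50% and 80% against 1.65 and 1.58 in log (difference 0.11, exact permutation p = 0.333). The amplitude difference was 0.062 without the Q 50% library and 0.072 without the log 80% library, and the repeat length difference was 0.5 bp without the log 80% library. The average +1 peak was 2.84 and 2.57 times the nuclear mean in Q and 2.77 and 2.33 in log, higher in Q at each digestion level (exact permutation p = 0.667). These permutations take no account of the digestion level.

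**Figure D3:**
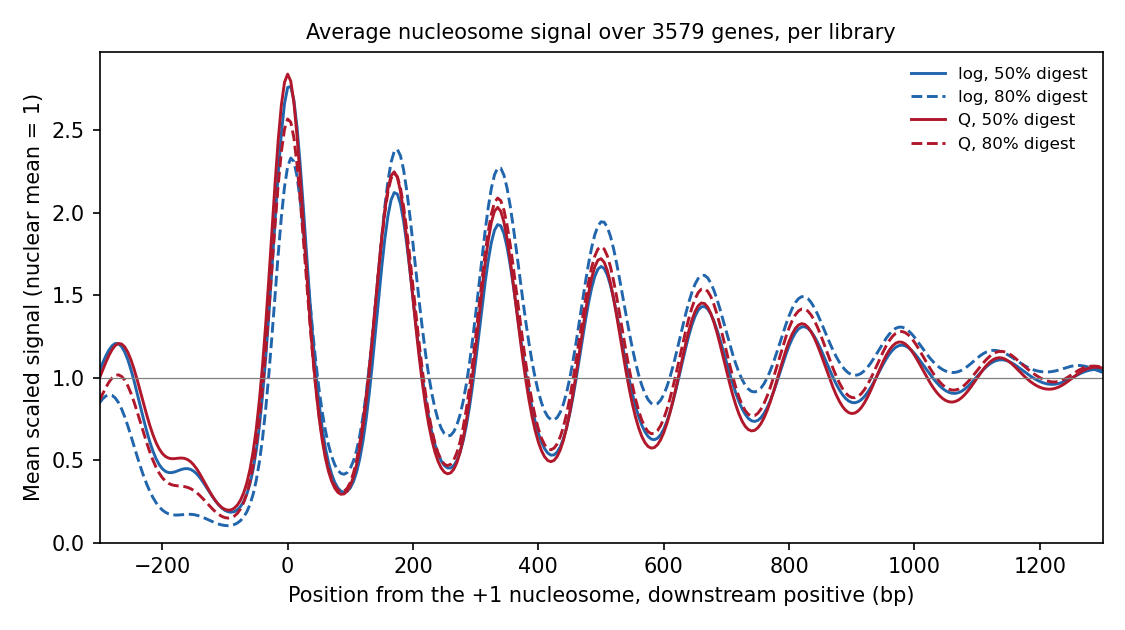
Mean scaled signal (nuclear mean = 1) against distance from the +1 nucleosome in bp over 3579 genes, one line per library, log in blue and Q in red, 50% digests solid and 80% digests dashed. The log 80% library has the lowest +1 peak (2.33) and its +2 peak (2.39) above it.

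Nucleosome calls, local maxima of the smoothed signal above the genome mean, numbered 60096 (log 50%), 35807 (log 80%), 61250 (Q 50%) and 58201 (Q 80%). As a mean of both directions, the Q libraries shared 88.7% of calls within 20 bp (chance 19.6%) and the log libraries 65.7% (chance 12.1%). These chance values are for the calls of the 50% library only. The log mean joins 49.1% of log 50% calls and 82.4% of log 80% calls, so it is held down by their unequal numbers. At matched digestion log and Q shared 71.2% at 50% and 58.4% at 80%, and crosswise 66.1% (log 50% with Q 80%) and 55.4% (log 80% with Q 50%). Of the log 80% calls alone, 82.4% had a call within 20 bp in log 50%, 72.3% in Q 80% and 69.9% in Q 50%. Signal in 100-bp bins correlated at r = 0.919 between the Q libraries and 0.601 between the log libraries, across bins of one genome, which are not independent replicates.

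Digestion level was measured on the same NDR windows. Signal in the 100-bp window was lower in the 80% digests than in the 50% digests, with a median difference of -0.34 over 5970 genes, and 0.012 with quantile normalization. The median was -0.96 with a pseudocount of 0.02 and -0.082 with one of 0.5. No gene passed the limma test for digestion, with 0 higher and 2243 lower at an unadjusted p under 0.05 (142 higher and 94 lower with quantile normalization), and edgeR was not run for this term. In ribosomal DNA the signal was 33.1 (log 50%), 87.4 (log 80%), 41.5 (Q 50%) and 40.1 (Q 80%) times the nuclear mean, and the 10 kb at chromosome ends held 0.985, 1.77, 0.962 and 1.11 times that mean, so the log 80% library stood apart from the other 3 on both.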

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

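The tests of a digestion effect shared with quiescent cells and of the log 80% library alone were chosen only after the results were seen, and the other tests here were set before their values were known. Of the patterns weighed, the first was the log 80% library, which had fewer nucleosome calls (35807) and a wider spread of coding-region signal between genes (SD 0.886) than the other 3 libraries. Lower depth was excluded for both, since the Q 80% library thinned to the same depth kept 58139 calls and had an SD of 0.41. A digestion effect that Q cells share remained open: the change from 50% to 80% digestion correlated across genes between log and Q (r = 0.701). It was larger in log cells, with an SD of 0.852 against 0.244, and 1 library per condition and digest cannot tell a stronger digest from a property of log cells.

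The second pattern was the +1 signal that differed in opposite directions at ribosomal protein and stress genes. The gap between the list medians was 1.62 (bootstrap SE 0.176 over genes) in the 50% pair, so it does not rest on the signal of the log 80% library alone. The windows were placed on the mean of all 4 libraries, log 80% among them, and the effect of that was not tested. The 50% medians were known when this check was chosen, so it describes that pair and is no independent test. Sharing of sequence between paralogs was excluded for ribosomal proteins, as the 19 genes with no A or B copy had a median of 0.99 in that pair. Whether nucleosomes that moved out of the fixed window account for it could not be decided, because at each library's own maximum the gap was 0.741 of that in the fixed window, between the limits set for either answer, although in the 80% pair it was 0.863. A difference between quiescent and growing cells may underlie the rest, as a hypothesis found and tested on the same data.

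The third pattern was the grouping of signal profiles around start codons. In 682 of 5970 genes the closest library pairs were the 2 conditions, against 126 by digestion level and 0 crosswise. The test is void, because the Q libraries were among the closest pairs in 92.8% of genes, which leaves the other pairings little chance to win. Log 50% was also closer to Q 50% (median r = 0.907) and Q 80% (0.845) than to log 80% (0.680), so that grouping by condition and by digestion level cannot be told apart here.

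The next results stood out because the digest pairs moved in opposite directions, each with 1 library per condition and digest, so that these differences were not tested. The median over tRNA genes was 0.54 at 50% and -0.79 at 80%. At terminators it was -0.090 at 50% and 0.28 at 80%. On the +1 signal the gluconeogenesis list had -0.40 at 50% and 0.57 at 80%, below the all-gene 0.056 and 0.84 in both. Over gene bodies the ribosomal protein list (18 genes) had 0.30 at 50% and -0.24 at 80%. The autophagy list over gene bodies had -0.19 at 50% and 0.35 at 80%. Ribosomal DNA had a log2 ratio of Q over log of 0.33 at 50% and -1.12 at 80%. The mitochondrial genome stood out for another reason, as data that no comparison used, and its signal had a ratio of Q over log of 1.65 at 50% and 1.84 at 80%.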

How the results depend on the processing

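The list tests other than on the 100-bp NDR window, edgeR, thinning, scaling relative to the 1000 bp around the start codon, the results on the 200-bp window and the fits without a library for arrays and calls were chosen only after the data were seen, and the other alternatives were planned. Of the alternatives' values for counts of genes and lists, arrays and calls, 85 kept a similar total, which does not mean the same genes or direction, 33 gave more calls, 35 fewer and 2 moved by more than the spread between libraries. For each change below the cause was not tested. The 100-bp windows hold few positions, and the log 80% library has the fewest positions of the 4 (17.6 M). Thinning to that depth left the count in the 100-bp window at 0, which shows nothing about depth, as limma recovered 0% of simulated changes there. Unadjusted counts went from 316 higher and 30 lower to 461 and 69.

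Genes past the threshold numbered 0 in the 100-bp NDR window, 28 in the 200-bp window, 1 for the +1 signal, 1 for gene bodies, and 0 for terminators, tRNA genes and positions. Quantile normalization gave 1, 137, 483, 13, 24 and 36 for the first 6 of these. Scaling relative to the 1000 bp around the start codon gave 34 in the 100-bp window, 8 for the +1 signal, 3 for bodies and 2 for terminators. A pseudocount of 0.02 gave 0 for the +1 signal and 2 for bodies, and one of 0.5 gave 6, 2 and, for terminators, 3. Values as deposited gave 0 for the +1 signal, 2 for bodies and 2 for terminators. Variance moderation by eBayes without trend or robust fitting gave 127 for the +1 signal and 0 for bodies. By edgeR on recovered positions the 200-bp window had 0, the +1 signal 13 and bodies 0, and thinning to the shallowest library gave 2 for bodies. The fixed window from 200 to 100 bp upstream gave 8 NDR genes and the 200-bp window 28.

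Fits without a library have no digestion term and compare unequal digests. Without each library in turn the counts ran from 0 to 276 (100-bp window), 0 to 1341 (200-bp window), 0 to 4249 (+1 signal), 0 to 2136 (bodies) and 0 to 125 (positions). Lists past the threshold ran from 0 to 5 (100-bp window, 5 with all libraries), 2 to 9 (+1 signal, 8), 3 to 6 (positions, 5), 5 to 14 (bodies, 6) and 1 to 11 (200-bp window, 9). The all-gene medians ran from -0.043 to 0.28 (100-bp window), 0.042 to 0.77 (200-bp window), -0.019 to 0.95 (+1 signal), -0.0020 to 0.080 (bodies), -0.21 to 0.44 (terminators) and -0.91 to 0.60 (tRNA genes). The excess of calls shared within conditions over those shared between them, 14.5 percentage points, ran from 2.48 to 31.8.

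With an estimated correlation camera placed 0 lists in the 100-bp window, 0 on the +1 signal, 0 on positions, 0 on bodies and 0 in the 200-bp window, and fry placed 0 in the 100-bp window. The estimated form had little power with 1 residual degree of freedom, so these zeros do not decide whether the lists differ. Quantile normalization gave 2 lists in the 100-bp window, 13 on the +1 signal and 4 in the 200-bp window. Relative to the 1000 bp around the start codon 4 passed on the +1 signal, 2 on bodies and 2 in the 200-bp window. Without trend or robust moderation 3 passed in the 100-bp window.

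All-gene medians changed sign with quantile normalization in the 100-bp window (-0.022), for digestion (0.012) and at terminators (-0.024), and relative to the 1000 bp around the start codon on bodies (-0.059). Quantile normalization gives the libraries one distribution and so holds these medians near 0. A change of sign under it is therefore no test of direction. The amplitude difference was 0.025 when taken as the SD of the aligned profile and 0.11 as reported. These measures have unlike scales, as the SD ran from 0.557 to 0.601 over the libraries and the amplitude from 1.58 to 1.77. Their differences cannot be compared, although this alternative is among those counted above as moved.

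The digestion level is shared by replicate number between log and Q, and served as the replicate block of each fit. Libraries of one digestion level deviated together from their condition means, with r = 0.13 in the 100-bp window, 0.215 in the 200-bp window, 0.583 for the +1 signal, 0.771 for bodies, 0.305 at terminators, 0.216 for tRNA genes and 0.284 for positions. With no replicate block 0 genes passed in the 200-bp window, 0 for the +1 signal, 0 for bodies and 228 for positions, and 3 lists passed in the 100-bp window, 11 on bodies and 5 in the 200-bp window. It moved no other count of genes or lists past the threshold by over 1.5 times. Unadjusted counts fell with it, for instance in the 100-bp window to 32 higher and 11 lower.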

Other observations

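The shape of the nucleosome pattern within 500 bp of the start codon differed most between log and Q cells at the genes of stress and storage metabolism. In the 50% digests the correlation of the log and Q profiles had a median of 0.521 over 61 general stress genes, 0.644 over 21 trehalose and glycogen genes, 0.710 over 36 stationary phase genes, 0.724 over 23 glycolysis genes and 0.788 over 137 ribosomal protein genes, against 0.907 over all genes. At the other end lay secretion (0.954), proteasome (0.947) and mitochondrial ribosomal protein genes (0.942). Between the Q libraries the list medians ran from 0.854 to 0.959. These values were chosen after the data were examined, were not tested, and come from 1 library per condition in the 50% digests.

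Some coding regions had extreme signal in each library, reported as values only. Of 5983 genes, 7 were under 0.05 in all 4 libraries, among them COS12, PDR18 and AIF1, and 18 were above 1.9. The latter include CUP1-1 (6.04, 17.9, 7.17 and 7.87 in log 50%, log 80%, Q 50% and Q 80%), CUP1-2 (5.96, 17.3, 7.37 and 7.78) and HIS3 (2.13, 6.10, 2.20 and 2.64). The CUP1 copies are near-identical and uncertain.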
